A study of Mus musculus with 2 samples.

How the data were processed

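DNase-seq libraries of whole cerebellum were used from male B6CASTF1/J mice of 8 to 10 months, 1 library for each of 2 biological replicates. Each library came from its own pool of 2 biosamples per the labels, which do not say whether the pools shared animals, so the spread between replicates may be partly technical. Replicate numbers are those of the labels. For each library the authors deposited 2 peak lists, a table of false discovery rates of the local cut rate, and a list of footprints. The assembly was mm10 per the labels. Each list was made from 1 library without pooling of replicates, per the deposited text that comes with the files. Aligner, peak caller, footprint caller, their versions, any mappability filter and the number of reads are not given in the sources used here.

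The peak lists hold the authors' signal value for each peak, a coverage measure that is never negative. Its scale is not given in the sources used here. In both replicates every value under 100 steps (100%) lay within 0.05 of a whole multiple of a single step, of 0.00714 in replicate 1 and 0.00632 in replicate 2, as a count of cuts divided by a number tied to depth would. Under that reading, replicate 2 was sequenced 1.13 times as deeply, and the median peak held 196 and 152 cuts, with a counting error of 7.14% and 8.11%. Cuts are not independent molecules where fragments are amplified, so counting errors are lower limits. Signal was used to rank peaks within a library and to describe them, and ratios between replicates were read relative to their median. Position of the summit was not used, since that column held a placeholder, and the middle of a peak served as its centre.

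The 2 peak lists per library were told apart by the deposited false discovery rate (FDR, a q-value) of the cut rate, which lists intervals with FDR under 0.05 alone, 22003960 in replicate 1 and 25142172 in replicate 2. In the stricter list every peak held a base with FDR under 0.001. In the longer list, of 99710 and 114935 peaks, every peak held a base with FDR under 0.05, and 64.1% and 63.9% held one under 0.001. The stricter list was used throughout and the longer list as an alternative. Of the stricter peaks 98.6% and 98.0% overlapped the longer list, and 3374 and 3530 overlapped another peak of their own list. The footprint lists carry the same value, 0.01, for every footprint, read from its place as the FDR threshold at which the authors called it, so footprints could not be ranked by strength. The deposited description of the files was read by hand and not used in any computation.

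Positions were compared with the GRCm38 (mm10) reference sequence and GENCODE mouse release 21. All intervals lay within the reference chromosomes, on 21 chromosomes. Gene starts were every annotated transcript start, 132721 in all, and gene lists were tested among 21911 coding genes of chromosomes 1 to 19, X and Y. The mice carry a CAST genome beside the B6 genome on which the reference is based. Neither allele was resolved, and how reads with CAST variants were aligned is not given in the sources used here.

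A promoter peak was centred within 1 kb of a transcript start, and any other peak was distal. A gene had a TSS peak where a peak overlapped the window of 1 kb either side of any of its starts, and its signal was that of the strongest such peak, with 0 where there was none. Peaks and footprints counted as shared with an overlap of 1 bp or more. Chance sharing of peaks came from 100 random placements on the same chromosome. Shared footprints were set beside 100 random placements of all footprints inside the stricter peaks. For footprints inside peaks of both replicates, 20 placements were used. Shares of peaks by annotation carry 95% Wilson intervals, which cover counting error only.

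Gene lists (18 of 20 symbols each) named cell types and functions: granule cells, Purkinje cells, cerebellar interneurons and unipolar brush cells, Bergmann glia and astrocytes, oligodendrocytes, microglia and macrophages, vascular cells, choroid plexus with ependyma and meninges, forebrain and midbrain neurons, Hox genes, anterior hindbrain patterning, other organs, housekeeping, immediate early genes, the circadian clock, glutamate receptors, GABA-A and glycine receptors, and hereditary ataxia. The clock list held a gene under both its old and its new symbol and so counted 19 genes. Some genes stand in more than 1 list: Gabra6, Grin2c, Tbp and Itpr1. A further 4 families were taken by symbol, namely 1092 olfactory receptors, 326 vomeronasal receptors, 57 keratin-associated proteins and 80 ribosomal proteins. The 30 motifs were short consensus sequences, matched without mismatch on both strands. The lists, motifs, tests, main settings and all alternatives except those named in the closing section were fixed before the data were examined. Genes named were, in each list, the 3 with the highest mean TSS signal and up to 2 without a TSS peak in either replicate, first in the alphabet. To these were added the 10 genes outside the lists with the most distal peaks by the lower of their 2 counts, the 10 strongest shared peaks, and the 5 highest and 3 lowest motifs. Some genes that this rule names are not reported here. Other list members and motifs were named after their values were seen.

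TSS peaks of a list were compared with all other coding genes by Fisher's exact test, two-sided. Distal peaks within 50 kb of the outermost gene start were compared with 10000 random lists of equal size from the coding genes, by a two-sided permutation p. Motifs in footprints, widened by 5 bp each side, were compared with as many intervals of equal length, by Fisher's exact test. All footprints were used, and the intervals were drawn from the stricter peaks of the same library, outside footprints. Log2 odds were taken with 0.5 added to each count, and odds printed without log2 are means of the uncorrected odds of the 2 replicates. Motifs in the central 150 bp of distal peaks were compared with promoter peaks in the same way. Each test was run in each replicate, p-values were adjusted by Benjamini and Hochberg's method over the 22 lists and families or the 30 motifs, and a call needed adjusted p under 0.05 in both replicates in the same direction. No test between groups exists, because the series as used here has 1 group.

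Alternatives were the longer peak list, the stronger part of each list above its median signal, equal numbers of peaks, each replicate alone, reciprocal overlap of 50%, and windows of 500 bp and 2 kb. Others were a single TSS per gene, random lists matched on CpG content, gene length or nearby starts in 5 bins, distances of 25 and 100 kb, footprint flanks of 0 and 10 bp, matched intervals of equal GC content, reversed consensus sequences, and motif windows of 75 and 300 bp.

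The tests of gene lists and motifs were tested on simulated data with known answers. Of promoter lists of 20 genes set to 95% open, 76 of 80 were called, and of those set to 20% open, 44 of 80. At 80% and 40% open, 0 of 80 and 1 of 80 were called, so lists within these bounds can pass unseen, and 0 of 280 unchanged lists were called at either setting. For promoter lists, also the matched ones below, openness was drawn separately for each replicate. In the data the replicates were alike, with 55.9% of coding genes open in both and 40.3% in neither. Separate draws make a call in both replicates rarer, so these rates do not give the error or power of the real calls. Distal counts raised 3-fold were called in 23 of 40 lists and those raised 2-fold in 3 of 40, with 3 of 180 and 0 of 180 false calls. Matched random lists were tested with all lists drawn from 1 of 5 bins: 80 of 80 promoter lists raised from 40% to 95% open and 43 of 80 raised to 80% were called, as were 36 of 80 distal lists raised 3-fold and 9 of 80 raised 2-fold, with 0 of 360 false calls at each size. Motifs planted in 2% or 0.5% of 50000 intervals were found in 3 of 3 cases each, with 0 of 27 false calls. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, bedtools 2.31.1, BLAST 2.17.0 and matplotlib 3.10.9.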

Results

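DNase-seq maps accessible chromatin by cutting the DNA of isolated nuclei with DNase I and sequencing the cut ends. It was applied to the cerebellum of male B6CASTF1/J mice, an F1 hybrid of the B6 and CAST strains, aged 8 to 10 months. The 2 libraries form 1 group and are biological replicates, each made from a pool of 2 cerebellum biosamples. With a single tissue and no treatment, the comparisons set the replicates beside each other, and gene groups, regions and sequence motifs beside the rest of the genome within each library. The authors' stricter peak list held 61776 peaks in replicate 1 and 71141 in replicate 2, with a median width of 200 and 220 bp and a total of 13.8 and 16.0 Mb. Footprints, short protected stretches inside cut regions, numbered 314116 and 320832, with a median length of 10 bp in both. Numbers of sequenced cuts were not given in the sources used here. The authors' signal per peak moved in whole steps within a library, and the median peak held 196 steps in replicate 1 and 152 in replicate 2. If a step stands for 1 cut, counting error at the median peak was 7.14% and 8.11%. Coordinates are those of the mm10 assembly, gene spans are those of the annotation, and values are means ± SD over the 2 replicates unless a single replicate is named. Signal ran higher in replicate 1, by a median log2 ratio of 0.43 over shared peaks, and SDs of signal include that difference.

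Chromatin was open at the promoters of cerebellar granule cell genes. All 20 genes of the granule cell list had a peak within 1 kb of a transcription start site (TSS) in both replicates, against 57.7% of the other coding genes (mean of 2 replicates). Signal of the strongest TSS peak was 11.1 ± 1.55 at Cbln3 (chromosome 14, 55878913 to 55884392), which encodes a cerebellin that granule cells secrete. It was 10.6 ± 2.49 at Tiam1 (chromosome 16, 89787111 to 90143769), an activator of the GTPase Rac, and 8.96 ± 0.66 at Neurod1 (chromosome 2, 79452521 to 79456751), a bHLH factor of granule cell differentiation. Zic2 and Zic1, zinc finger factors kept on in mature granule cells, had 6.84 ± 1.16 and 6.3 ± 0.787, and Pax6, a paired-box factor, had 5.26 ± 1.02. Gabra6 (chromosome 11, 42306437 to 42321072), the GABA-A receptor subunit typical of granule cells, had 2.23 ± 1.2. By Fisher's exact test the list stood above the other coding genes in each library, with adjusted p = 5.63e-05 and 2.99e-05. Among random lists with the same CpG content, 77.0% and 75.3% of genes had such a peak, and permutation gave adjusted p = 0.0033 and 0.00135.

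Marker genes of the other neurons and of the astrocytes of the cerebellum were not called apart from other coding genes in both replicates. Of the 20 Purkinje cell genes, 12 had a TSS peak in replicate 1 and 10 in replicate 2, a mean of 55% ± 7.07 (SD, n = 2). Itpr1 (chromosome 6, 108213096 to 108551109), the inositol trisphosphate receptor abundant in Purkinje cells, had a signal of 7.76 ± 0.732, the homeobox gene Lhx1 had 5.19 ± 1.06, and Rora, the nuclear receptor mutated in staggerer mice, had 3.1 ± 0.792. Car8, Gad1 and Pcp2, the last named for its expression in Purkinje cells, had no TSS peak in either replicate. The list of interneurons and unipolar brush cells gave 45% and 30%, with 2.98 ± 1.3 at Calb2 (calretinin) and 1.43 ± 0.407 at Eomes, a factor of unipolar brush cells. Gad2, which makes GABA, and Grm2 had no TSS peak. The list of Bergmann glia and other astrocytes gave 55% and 70%, led by Nfia, a factor of gliogenesis, at 8.76 ± 0.012, Aldoc, also an enzyme of Purkinje cells, at 4.99 ± 0.646, and Gfap at 2.19 ± 0.824. The astrocyte genes Aldh1l1 and Aqp4 had none. Fisher's exact test gave adjusted p = 1 and 0.683 for the Purkinje list, 0.317 and 0.0277 for interneurons, and 0.861 and 0.311 for astrocytes, so none passed in both replicates. Against random lists of like CpG content the interneuron list was lower, with 83.4% and 81.5% in the random lists (permutation, adjusted p = 0.000733 and 0.00055). It was also lower in the stronger part of each peak list and in replicate 2 taken alone. In the longer peak list the share of interneuron genes rose to 57.5% ± 3.54 (SD, n = 2).

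Lists of the rarer glia, vessels and linings of the brain had fewer open promoters than other coding genes. Of the 20 oligodendrocyte genes, 5 in replicate 1 and 4 in replicate 2 had a TSS peak, a mean of 22.5% ± 3.54 (SD, n = 2). Sox8, a factor of the oligodendrocyte lineage, had 1.54 ± 0.483, Mbp (chromosome 18, 82475146 to 82585637), which encodes myelin basic protein, had 1.47 ± 0.567, and the precursor receptor gene Pdgfra had 1.05 ± 0.0667. The myelin genes Aspa and Cldn11 had none. In the microglia and macrophage list, TSS peaks were found in replicate 1 alone and at 2 genes, the complement gene C1qc (0.892) and Irf8 (0.6), a factor of myeloid cells, while 18 genes including Aif1 and C1qa had none. In the vascular list they were found in replicate 2 alone, at Tagln (1.24), a smooth muscle gene, and at the pericyte gene Kcnj8 (0.234), and not at Abcc9 or Acta2. The list of choroid plexus, ependyma and meninges had 25% and 20%, with Col1a1, a collagen of meningeal fibroblasts, at 3.45 ± 1.21, Foxj1, a factor of ciliated cells, at 3.15 ± 1.18, and Otx2 at 1.08 ± 0.0689. Aldh1a2 and Ccdc153 had no TSS peak. Adjusted p by Fisher's exact test was 0.00679 and 0.0014 for oligodendrocytes and for choroid plexus and meninges, 2.68e-05 and 1.57e-07 for microglia, and 8.84e-08 and 4.99e-05 for vessels. Random lists of like CpG content had 31.7% and 31.5% open for microglia and 46.6% and 45.8% for choroid plexus and meninges. For vessels they had 51.9% and 51.1%, and for oligodendrocytes 59.6% and 58.3%. Each list was still lower by permutation, with adjusted p = 0.0303 and 0.0008 for microglia. In the authors' longer list, oligodendrocyte genes reached 45% ± 7.07 and choroid plexus and meninges genes 42.5% ± 17.7 (SD, n = 2), and both calls ended. Vascular genes reached 25% ± 7.07 there and microglia genes 12.5% ± 3.54. With a window of 2 kb the oligodendrocyte call ended as well.

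Genes of other brain regions and other organs were mostly closed at their promoters. None of 20 Hox genes, which pattern the hindbrain and trunk behind the cerebellum, had a TSS peak in either replicate, Hoxa13 among them. The list of forebrain and midbrain neurons had 20% in both replicates, with 15 genes closed in both, among them Bcl11b and Dlx1. Its highest member was Neurod2 (chromosome 11, 98325415 to 98329648), a bHLH factor that granule cells also express, with 6.43 ± 1.27, and the dopamine receptor gene Drd1 had 1.04 ± 0.473. Markers of liver, muscle, blood, gut, heart, pancreas and germ cells had a TSS peak at 1 of 20 genes in each replicate, the creatine kinase gene Ckm with 1.79 ± 0.623, and none at Actc1 or at Alb, which encodes albumin. Genes that set up the anterior hindbrain, where the cerebellum arises, had 45% and 40%, with 6.61 ± 2.66 at Pbx3 and 6.02 ± 1.69 at En2 (chromosome 5, 28165694 to 28172166), and none at the growth factor genes Fgf8 and Fgf17. Fisher's exact test gave adjusted p = 8.84e-08 and 1.57e-07 for Hox genes, 0.00135 and 0.0014 for forebrain and midbrain, and 2.21e-06 and 3.73e-06 for other organs. For the anterior hindbrain it gave 0.317 and 0.212, and against random lists of like CpG content (77.3% and 75.4%) the list was lower, with a permutation adjusted p of 0.00147 and 0.00055. In the longer peak list the forebrain and midbrain genes reached 37.5% ± 10.6 (SD, n = 2) and that call ended.

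Genes used by nearly every cell, and those of neuronal activity and the daily clock, were open throughout. All 20 housekeeping genes, all 20 immediate early genes, all 19 clock genes and all 20 hereditary ataxia genes had a TSS peak in both replicates, as did 77 of 80 ribosomal protein genes. Signal was 15.3 ± 4.36 at Rplp0, 12.7 ± 4.44 at Eef2 and 11.8 ± 0.732 at Rpl13a, all of the translation machinery. Jun (chromosome 4, 95049034 to 95052222), Dusp1 and Egr1, induced within minutes of stimulation, had 16 ± 1.91, 11 ± 1.73 and 10.3 ± 2.53. Per1 (chromosome 11, 69095217 to 69109960), Nr1d2 and Per2, of the clock's feedback loops, had 15.9 ± 0.748, 14.8 ± 0.851 and 13.7 ± 2.45. Among the ataxia genes Atm, a kinase of the DNA damage response, had 11.5 ± 1.56, and the tau tubulin kinase gene Ttbk2 had 9.09 ± 2.52. Fisher's exact test gave adjusted p = 9.67e-05 and 4.91e-05 for the clock list and 3.84e-14 and 1.17e-14 for ribosomal proteins. For housekeeping, immediate early and ataxia genes it gave 5.63e-05 and 2.99e-05 each. Against random lists of like CpG content the immediate early call ended, with a permutation adjusted p of 0.0577 and 0.0381.

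Neurotransmitter receptor genes were not called apart from other coding genes, with 62.5% ± 3.54 for glutamate receptors and 67.5% ± 3.54 for GABA-A and glycine receptors (SD, n = 2). Grin2a and Grin1, NMDA receptor subunits, had 4.47 ± 0.891 and 3.92 ± 0.986, and the AMPA receptor gene Gria2 had 3.72 ± 0.651, while Gria1 and Gria3 had no TSS peak. Gabrd (chromosome 4, 155384980 to 155398112), the subunit of tonic inhibition in granule cells, had 5.76 ± 0.034, while Gabra3 and Gabra5 had none. Sensory receptor genes had few open promoters: 1082 of 1092 olfactory receptor genes and 325 of 326 vomeronasal receptor genes had no TSS peak in either replicate. Of 57 keratin-associated protein genes, which build hair, 54 had none. Fisher's exact test gave adjusted p = 0.718 and 1 for glutamate receptors, 0.425 and 0.56 for GABA-A and glycine receptors, 1.38e-122 and 1.75e-118 for vomeronasal receptors, and 4.35e-18 and 5.06e-16 for keratin-associated proteins. Random lists of like CpG content had 10.5% and 10.5% open for olfactory receptors, 9.91% and 9.89% for vomeronasal receptors and 17.7% and 17.7% for keratin-associated proteins. The shares themselves were 0.733% and 0.824%, 0.307% in both replicates, and 3.51% and 5.26%, still lower by permutation (adjusted p = 0.000733 and 0.00055 for both receptor families, 0.00338 and 0.0106 for keratin-associated proteins). Across the 22 lists and families, p-values treat genes as the units and so describe each library, and a peak that is missing from a list of a mixed tissue does not show that the promoter is closed in every cell.

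**Figure D1:**
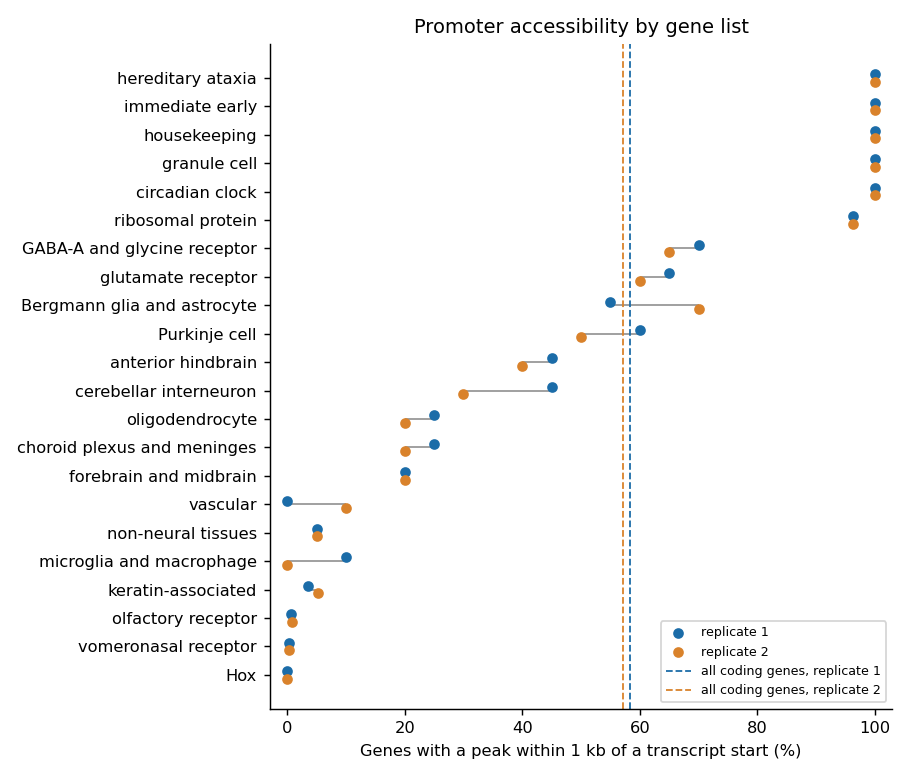
Share of each gene list (percent, horizontal axis) with a peak of the stricter list within 1 kb of a TSS, a dot for each replicate, with dashed lines at the share of all coding genes in each replicate. Granule cell, housekeeping, immediate early, clock and ataxia genes sit at 100%, and Hox genes at 0%.

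Granule cell genes also had the most distal peaks around them. Distal peaks, centred over 1 kb from every TSS, numbered 11.9 ± 1.20 (SD, n = 2) within 50 kb of a granule cell gene's TSS, 4.67 times the 2.55 of random gene lists. Barhl2 (chromosome 5, 106452523 to 106458166), a homeobox gene of the rhombic lip lineage, had 19 and 34 in replicates 1 and 2, and Nfix, of the nuclear factor I family, had 35 and 12. The neighbours Zic1 and Zic4 on chromosome 9 had 15 and 31 over largely the same interval, Neurod1 had 10 and 20, and Gabra6 had 2 and 2. Immediate early genes had 7.45 ± 1.41 (2.90 times random lists), with 27 and 38 at Egr1 (chromosome 18, 34859823 to 34864984) and 15 and 22 at Junb. Clock genes had 7.39 ± 2.05 (2.87 times), with 22 and 31 at Per1, 16 and 40 at Nr1d1 and no distal peak at Clock, Nr1d2 or Rorb. Families with fewer than random lists were the olfactory receptors at 0.230 ± 0.068, the vomeronasal receptors at 0.0982 ± 0.013 and the keratin-associated proteins at 0.781 ± 0.062.

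The remaining 16 lists were not called, among them Purkinje cell genes at 1.45 ± 0.283, oligodendrocyte genes at 2.25 ± 0.141, microglia genes at 3.38 ± 0.0354 and housekeeping genes at 4.08 ± 0.177. Permutation p-values, from 10000 random lists, gave adjusted p = 0.0011 and 0.00088 for granule cell genes, where the raw p of 0.0002 was the smallest that they can give. Adjusted permutation p was 0.0114 and 0.00147 for immediate early genes and 0.0477 and 0.00088 for clock genes. The clock call ended at 25 kb, at 100 kb and in the longer peak list, and the immediate early call ended at 100 kb. Hox genes were lower in replicate 2 alone (0.95 against 2.64 in random lists, permutation adjusted p = 0.0302) and not in replicate 1 (1.5 against 2.50).

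**Figure D2:**
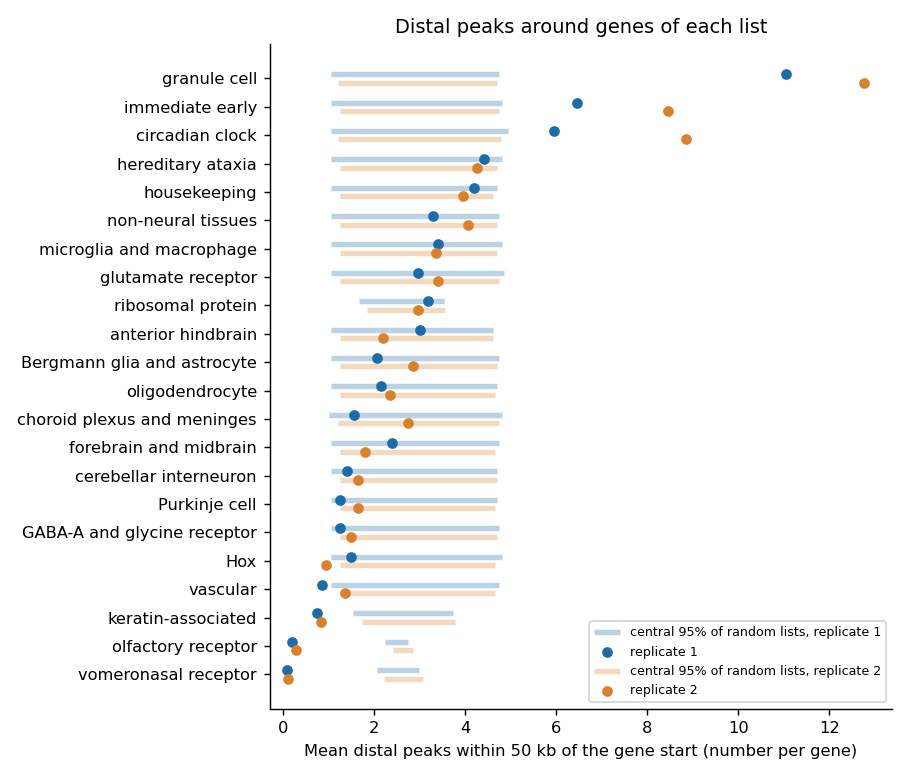
Mean number of distal peaks within 50 kb of the TSS per gene (horizontal axis) for each list, a dot for each replicate, with bars for the central 95% of 10000 random lists. Granule cell genes lie at 11.1 and 12.8, to the right of every other list.

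Outside the lists, the most distal peaks lay around Bcl9l, Nfic and Tab1. Bcl9l (chromosome 9, 44482825 to 44511896), a Wnt pathway coactivator, had 37 and 45 distal peaks within 50 kb, Nfic (chromosome 10, 81396186 to 81455635), of the nuclear factor I family, had 52 and 34, and Tab1 (chromosome 15, 80133127 to 80161707), an adaptor of the kinase TAK1, had 33 and 32. The neighbours Bcdin3d (chromosome 15, 99470079 to 99474730) and Faim2 (chromosome 15, 99497012 to 99528165), an inhibitor of apoptosis in neurons, had 36 and 31, and 37 and 30. Rara (chromosome 11, 98927818 to 98974942), a retinoic acid receptor gene, had 30 and 36, and Apba2 (chromosome 7, 64501706 to 64753878), a neuronal adaptor of the amyloid precursor protein, had 34 and 30. Another interval held the neighbours Ccr10, Cntnap1 and Plekhh3 (chromosome 11, 101162679 to 101190724), each with 30 and 31. All 10 of these genes had a TSS peak in both replicates, from 1.97 ± 0.325 at Rara to 7.42 ± 0.0769 at Cntnap1.

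Footprints held the sites of promoter factors, CTCF and nuclear factor I far more often than matched intervals of the stricter peaks. Of all footprints tested, 64.1% and 66.7% lay inside those peaks, so the sets compared differ in region too. The full palindromic nuclear factor I site had mean log2 odds of 6.15 ± 0.20 (SD, n = 2) against matched intervals, yet it was rare, with 96 and 117 footprints. NRF1 sites, bound by a factor of mitochondrial and housekeeping genes, had log2 odds of 5.70 ± 0.17. CTCF sites, bound by the factor that bounds chromatin loops, had 5.43 ± 1.14 and stood in 1.29% of footprints against 0.0342% of matched intervals. CRE sites of the CREB and ATF factors had 4.15 ± 0.41 and SP and KLF sites 3.40 ± 0.10. Sites of factor families with members in the granule cell list were also enriched. The CAGATG E-box of NEUROD1, ATOH1 and related bHLH factors stood in 1.11% against 0.472% (mean odds 2.37). The nuclear factor I half-site, of a family that also includes Nfia of the astrocyte list, stood in 3.34% against 1.29% (odds 2.64). The ZIC site had odds of 1.76. Which cells these footprints came from was not tested. The lowest odds belonged to ROR sites (0.363), GATA sites (0.399), of blood and endothelial factors, and SOX sites (0.467).

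Fisher's exact test called 15 of 30 motifs enriched and 9 depleted in both replicates. The single matched interval behind the full nuclear factor I site in each library makes its odds uncertain, with a standard error of 1.19 in log2 units, so its order against NRF1 and CTCF is open. CTCF odds differed between the replicates, at 76.1 in replicate 1 and 24.9 in replicate 2, although 4207 and 3981 footprints held the site. The difference lay mostly in the matched intervals, of which 0.0342% ± 0.0231 (SD, n = 2) held it. With matched intervals of equal GC content the calls of ROR, AP-1 and the CAGCTG E-box ended and that of TEAD turned from depleted to enriched. P-values here treat footprints as the units and describe each library.

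**Figure D3:**
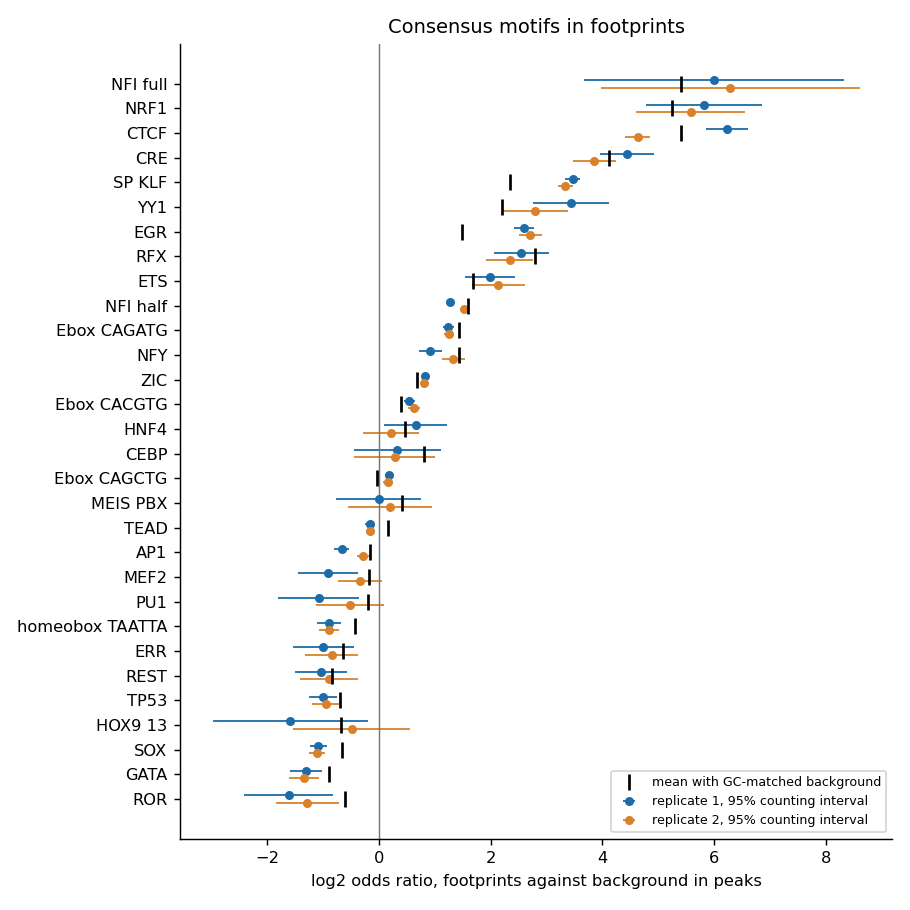
Log2 odds of each motif in footprints against matched intervals of the stricter peaks (horizontal axis), a point for each replicate with its 95% counting interval, and a black tick for the mean against intervals of equal GC content. NFI_full, NRF1 and CTCF lie highest, with mean log2 odds of 6.15, 5.70 and 5.43.

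Distal and promoter peaks carried different sites. In distal peaks CTCF sites were found in the central 150 bp of 8.63% against 1.74% of promoter peaks (odds 5.31, log2 2.41 ± 0.07, n = 2). The CAGATG E-box was found in 10.6% against 2.59% (odds 4.47, log2 2.16 ± 0.02), the nuclear factor I half-site in 19.6% against 8.67% (2.56) and the ZIC site in 14.0% against 7.49% (2.01). ROR sites, bound by the product of Rora among others, had odds of 3.65, the homeobox site TAATTA 2.81, AP-1 sites of the FOS and JUN factors 2.34 and MEF2 sites 2.20. Promoter peaks more often held sites of YY1 (odds of distal against promoter 0.0513), ETS factors (0.0704), NRF1 (0.0869), SP and KLF factors (0.0991), EGR factors (0.107) and CREB and ATF factors (0.177). Fisher's exact test called 14 of 30 motifs higher in distal peaks and 9 higher in promoter peaks. GC content was not matched between distal and promoter peaks, and its part in these odds was not tested. The calls of the full nuclear factor I site, GATA and the CAGCTG E-box each ended under 1 alternative.

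Peaks gathered at promoters, where 40.4% ± 3.30 (SD, n = 2) of them were centred although this class makes up 6.05% of the genome. The 95% Wilson interval was 42.4 to 43.1% in replicate 1 and 37.7 to 38.4% in replicate 2, which covers counting error only. With equal numbers of peaks the shares were 42.8% and 40.8%, against 42.8% and 38.1% with all peaks. Introns held 31.2% ± 2.35 of peaks, intergenic sequence 22.5% ± 1.57 and exons 5.86% ± 0.617, against 38.3%, 52.4% and 3.18% of the genome. Of 21911 coding genes, 12239 (55.9%) had a TSS peak in both replicates and 8835 (40.3%) in neither. The share at promoters moved from 31.8% with a window of 500 bp to 48.3% with one of 2 kb.

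The strongest shared peaks lay at coding genes, noncoding genes and a pseudogene. The highest mean signal, 46.4 ± 11, lay 117 bp from the start of the long noncoding RNA gene Gm42418 (chromosome 17, 39846781 to 39846900). Next came a peak 21 bp from the TSS of Dynlt1b (chromosome 17, 6430001 to 6430180), a dynein light chain gene, with 39.6 ± 4.93. Peaks at the TSSs of Acin1 (chromosome 14, 54686601 to 54686880), an apoptosis and splicing factor, Dnpep (chromosome 1, 75317521 to 75317940), an aspartyl aminopeptidase, Gm21887 (chromosome X, 170009841 to 170010160) and Hjurp (chromosome 1, 88277521 to 88277760), a centromere chaperone, had 23.9 ± 6.41, 23.5 ± 2.98, 23 ± 1.88 and 21.2 ± 6.4. The other strong peaks lay 10173 bp from the TSS of Cox14 (chromosome 15, 99735661 to 99735920) with 24.6 ± 2.82, 7211 bp from that of Lars2 (chromosome 9, 123461881 to 123462120) with 24.2 ± 8.11, 20595 bp from the microRNA gene Gm25352 (chromosome 3, 5860361 to 5860530) with 23.8 ± 4.24, and 163 bp from the pseudogene Gm21769 (chromosome 8, 20122141 to 20122300) with 20.6 ± 7.35. Of these 10 peaks, 7 lay within 1 kb of a transcript start, 5 of them of a coding gene. The sequence under 6 of them, those at Gm42418, Dynlt1b, Lars2, Gm25352, Gm21887 and Gm21769, had at least 1 more near-identical place in the assembly.

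The replicates shared most of their peaks, and above all the strong ones. A peak of the other replicate overlapped 76.0% of peaks in replicate 1 and 66.1% in replicate 2, against 1.34% and 1.16% when the other list was placed at random. With each list split by signal into 4 equal parts, 99.0% and 97.8% of the strongest part were shared, and 44.0% and 31.3% of the weakest. Promoter peaks were shared at 80.5% and 79.0% and distal peaks at 72.5% and 58.2%, with a median signal of 2.08 and 1.41 at promoters and 1.11 and 0.790 at distal sites. Across 45465 peaks that matched 1 to 1, signals ranked alike, with Spearman's rho of 0.918 and Pearson's r of 0.925 on the log2 scale. These are correlations across peaks, which are not independent replicates. The median log2 ratio of replicate 1 to replicate 2 was 0.43, with an SD of 0.49 over peaks. If a step stands for 1 cut, signals of the shared peaks varied between the replicates by 15.9 times the variance of independent counts. In distal shared peaks the log2 ratio, centred on their median, was 0.46 at CTCF sites and -0.28 at CAGATG E-boxes. Under a reciprocal overlap of 50% the mean share of peaks shared was 57.9%.

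Footprints overlapped between replicates less than peaks did. A footprint of the other replicate overlapped 50.99% of footprints in replicate 1 and 50.6% in replicate 2. With all footprints of the other replicate placed at random inside its stricter peaks, the shares were 24.8% and 24.7%. Footprints that lay outside those peaks were moved into them too, so these shares are not an exact chance level. Footprints lay inside the stricter peaks at 64.1% and 66.7% and inside the longer list at 82.8% and 84.1%. At least 1 footprint lay in 88.3% and 84.1% of the stricter peaks. Among footprints inside peaks of both replicates, a choice made after seeing the data, 68.5% and 71.6% were shared, against 32.3% and 34.6% at random. The random positions covered whole peaks, also the parts that only 1 replicate called, so these random shares may be too low.

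Peaks were sparse on the X chromosome, of which these males carry a single copy. X held 8.97 and 11.4 peaks per Mb in replicates 1 and 2, and the median autosome 25.6 and 29.1, a ratio of 0.371 ± 0.0293 (SD, n = 2). Every autosome lay above X, from chromosome 3 with 16.4 and 19.96 peaks per Mb to chromosome 11 with 42.7 and 45.8. On X 44.0% and 43.2% of coding genes had a TSS peak, against 59.5% and 58.3% on autosomes, and the median signal of X promoter peaks was 0.564 and 0.604 of the autosomal one. The Y chromosome held 27 and 40 peaks. In the stronger part of each list the ratio was 0.246, and per coding gene 0.554.

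**Figure D4:**
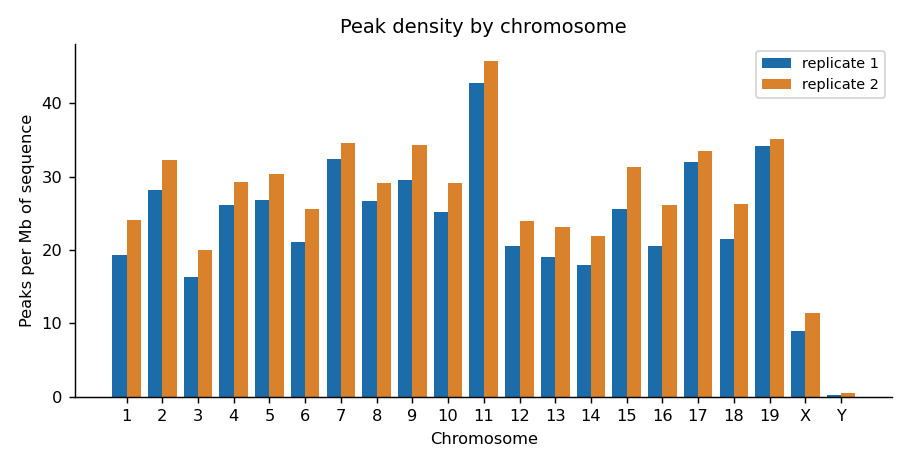
Peaks of the stricter list per Mb (vertical axis, from 0) on each chromosome, with a bar for each replicate. The X chromosome has 8.97 and 11.4 peaks per Mb and lies below every autosome in both replicates.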

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

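The tests on bases outside the peak lists were chosen only after the result was seen. The table of false discovery rates holds accessible bases that no comparison above used: 13.7 Mb in replicate 1 and 16.7 Mb in replicate 2 had an FDR under 0.05 and lay outside the longer peak list, which is 39.3% and 40.3% of all such bases. Of these bases, 97.02% and 96.8% lay within 500 bp of a peak of that list. The other replicate also listed 81.1% of those of replicate 1 and 64.4% of those of replicate 2, while it listed 1.56% and 1.32% of all sequenced bases. Most of these bases lie beside peaks, which the replicates largely share, so the share of all sequenced bases is not a chance level for them. Groups of 2 are too small for a test of outlying samples, so none was run.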

How the results depend on the processing

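Chosen only after the data were seen were the tests against the longer list of the other replicate, of footprints inside the peaks of both replicates or inside the stricter peaks, and of list members within 50 kb counted once. No paired analysis was possible because there is 1 group. The strength of footprints could not be varied because each carries the same value. Among lists, 189 of the tests on TSS peaks under alternatives gave the main call, 4 gained a call and 5 lost it. For distal peaks these numbers were 215, 1 and 4, and with close neighbours counted once granule cell genes had 11.1 ± 0.393 distal peaks over 18 genes and were still called. For motifs in distal against promoter peaks they were 139, 8 and 3. For motifs in footprints they were 126, 3 and 12, and 9 changed direction, all under reversed sequences or equal GC content.

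Peaks shared (71.03%) came to 83.0% in the stronger part of each list and 57.9% under reciprocal overlap, as a stricter match must lower it, and 82.1% against the longer list. Spearman's rho (0.918) was 0.923 in the longer list, 0.862 in the stronger part, whose range is narrower, 0.907 with equal numbers and 0.922 under reciprocal overlap. Footprints shared (50.8%) were 37.2% under reciprocal overlap and 70.1% inside the peaks of both replicates. Promoter peaks (40.4%) were 33.5% in the longer list, 52.2% in the stronger part, 31.8% with 500 bp and 48.3% with 2 kb, as the window itself sets. At 100 kb, 1 list had more distal peaks than random lists, where the main setting gave 3. The X ratio (0.371) was 0.246 in the stronger part, 0.332 with equal numbers and 0.554 per coding gene. Except where the construction shows it, the cause was not tested.

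Reversed consensus sequences left 3 motifs enriched, where the listed ones gave 15. These were SP and KLF, whose reversed sequence is the sequence itself, EGR and the nuclear factor I half-site. Log2 odds turned negative for the full nuclear factor I site (-2.32), NF-Y (-1.20), the CAGATG E-box (-1.10), CRE (-0.29), ZIC (-0.28), the CACGTG E-box (-0.27) and YY1 (-0.24), as a control without the site allows. Of these, NF-Y and the CAGATG and CACGTG E-boxes were called depleted. The full nuclear factor I value rests on 0 footprints in each library and so on the added constant. YY1 rests on 2 and 1 footprints, with opposite signs in the replicates. With equal GC content the CAGCTG E-box had -0.026 and TEAD 0.17, against 0.18 and -0.16 in the main setting; the cause was not tested.

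Without a replicate, promoter peaks ranged from 38.1 to 42.8% and the X ratio from 0.350 to 0.392. List counts ranged from 6 to 6 higher and 10 to 11 lower at the TSS, and 3 to 3 and 3 to 4 for distal peaks. Motif counts were 15 to 16 enriched and 9 to 12 depleted in footprints, and 15 to 16 distal and 9 to 10 promoter. The number of cuts is not known, so what depth limits was not tested. Of the weakest of 4 equal parts of the peaks, 44.0% and 31.3% were shared. In simulated data with openness drawn separately for each replicate, Fisher's exact test called 0 of 80 lists of 20 genes set to 80% open.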

Other observations

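Families below were chosen and tested only after the data were seen, and so were the tests of a larger granule cell share and of fewer genes on X. Among 26 families taken by symbol, 8 had more and 11 had fewer open promoters than other coding genes in both replicates (Fisher's exact test, adjusted over the families). No matching on CpG content, gene length or nearby starts was done for these families, so the part of these traits in the calls was not tested. Subunits of respiratory complex I were open at 98.9% ± 1.54 of 46 genes, mitochondrial ribosomal proteins at 100% of 78, proteasome subunits at 95% of 40 and Rab GTPases, which steer vesicles, at 88.1% of 59. Semaphorins, which guide axons, were open at 92.5% ± 3.54 of 20 genes (exact test, adjusted p = 0.00501 and 0.000612). Zinc finger proteins named Zfp were open at 84.3% ± 0.359 of 394, yet had 1.83 ± 0.144 distal peaks within 50 kb against 2.56 in random lists (permutation, adjusted p = 0.0013 and 0.00104). Potassium channels were not called at promoters (50.5% ± 0.752 of 94, exact test, adjusted p = 0.143 and 0.326) and had 4.59 ± 0.1504 distal peaks against 2.56 (permutation, adjusted p = 0.0013 and 0.00104).

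The clustered protocadherins, cell surface proteins that neurons express in random combinations, had a TSS peak at 14.8% of 54 genes in replicate 1 and 29.6% in replicate 2 (exact test, adjusted p = 1.61e-10 and 9.79e-05), and 0.759 ± 0.262 distal peaks. Other families with few open promoters were bitter taste receptors (0% of 35), beta-defensins (3.57% ± 1.68 of 42), keratins (7.55% of 53), chemokines (12.9% ± 2.02 of 35), serpins (13.1% of 61) and cytochromes P450 (22% of 100). Wnt ligands (28.9% ± 3.72 of 19), collagens (40% ± 3.14 of 45) and Fox factors (40.9% of 44) passed narrowly, with a higher adjusted p of 0.0472, 0.0435 and 0.0472 in the exact test. Sox factors (44.7% ± 3.72 of 19), cadherins (56.5% of 23) and ephrins with Eph receptors (65.9% ± 3.21 of 22) were not called.

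In distal shared peaks the signal ratio of the replicates depended on the kind of site, with log2 ratios (replicate 1 over 2, centred on their median and adjusted for GC content) of 0.53 at CTCF sites, -0.35 at MEF2, -0.33 at ROR, -0.25 at CAGATG E-boxes, -0.19 at AP-1, -0.17 at nuclear factor I half-sites and -0.01 at ZIC. A difference in GC content was not the whole cause, since the gap between CTCF and CAGATG peaks was 0.77 before and 0.80 after adjustment (95% interval 0.77 to 0.83), and neither was depth, since the smallest gap over 5 bins of mean signal was 0.50. A larger share of granule cells in the pool of replicate 2 is a candidate explanation. The median of peaks near granule cell genes lay lower than that of each of 7 lists of other cell types, by -0.29 against their median. The 95% interval of the granule cell median (-0.136 to -0.0168) lay below those of the Purkinje and astrocyte lists and overlapped the rest. Intervals of the 7 lists overlapped, but peaks near immediate early genes lay as low (-0.12, granule cell genes -0.09) and those near ribosomal protein genes as high (0.22) as cell type lists, so granule cells are not singled out. Sites of factor families with members in the granule cell list were mixed, since CAGATG E-boxes and nuclear factor I half-sites lay low and ZIC sites did not. AP-1 sites lay low as well, so the sites do not decide. Differences in digestion, fragment size or the animals pooled stay open and were not tested.

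The strongest shared peaks often lay in sequence with copies elsewhere. A second place in the genome at 95% identity was found for 6 of the 10 strongest peaks, against 2.22% of those ranked 11 to 100 and 1.8% of 500 drawn at random. Reads shared between near-identical copies, or copies collapsed in the assembly, may raise these signals. Whether these 10 peaks differ from others in their distance to coding promoters was not tested. Near-identical nuclear copies of mitochondrial DNA did not account for the signals, since 0 of the 10 peaks matched the mitochondrial genome at 95% identity over most of their central 150 bp. Shorter or more diverged copies would not have been found. No biological explanation was tested, and the peaks near Cox14, Acin1, Dnpep and Hjurp had no second place.

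Among peaks as called, none of 3 tested causes alone accounted for the sparse peaks on X. With X signals counted as if from a pair of chromosomes, the ratio of X to the median autosome among peaks above the median signal was 0.434 in replicate 1 and 0.454 in replicate 2, against 0.243 and 0.251 as measured. X sites too weak to be called were not in the list and could not be counted. The ratios with doubled signals may therefore be too low, and a single X is not excluded as the cause. Repeats mask 46.8% of X and 33.4% of the median autosome, yet with all peaks counted per Mb of sequence outside repeats the ratio was at most 0.486. Per coding gene, of which X has 5.80 and the median autosome 8.03 per Mb, it was at most 0.585. The causes together may explain more of it, since doubled signals per coding gene gave 0.678 and 0.683, and what remains, including few open genes on X, stays open.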
